A study of Homo sapiens with 24 samples.

How the data were processed

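RNA-seq and ATAC-seq were made from primary human proximal tubule epithelial cells of 2 non-diabetic and 2 diabetic donors, grown in a commercial renal epithelial medium, untreated or treated with TGFB1 for 24 h. Per the labels' protocols, total RNA was taken with an RNeasy kit and made into libraries with a TruSeq RNA kit for paired-end sequencing, and the ATAC-seq libraries were made from cells with an Illumina Nextera-type DNA kit. Each sample's disease group, treatment, donor and replicate number came from the labels. The RNA groups held 4 libraries each, replicates 1 and 2 from donor 1 and replicates 3 and 4 from donor 2, and the ATAC-seq groups 2 libraries each, 1 per donor.

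The deposited RNA files hold raw counts per gene in the layout of STAR's gene counting, with 1 column without regard to strand and 1 per strand. STAR, Bowtie, MACS2 and the build hg38 are named in the submitters' processing notes without versions, and no trimming, filter, duplicate step or annotation release is given. Reverse-strand counts (column 4) were used, since the forward strand held 4.7 to 5.23% of the stranded counts; whether the kit marks strand is not stated. The deposited counts are whole numbers, so the authors had not scaled them. Each of the 8 deposited ATAC-seq files is a narrowPeak list of MACS2 called on 1 library, so peaks were not called on pooled samples. Its deposited columns hold a score (10 times the -log10 q cut to a whole number), a fold enrichment at the summit, which is a ratio over the local background of that library, and the -log10 p-value and -log10 q-value. The lowest -log10 q was 1.3 in the deposited lists. Neither adapter shifts nor read filters for ATAC-seq are stated in the labels, and the lists give no read counts, so the depth of these libraries is unknown.

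Of 60725 gene rows, 56558 identifiers matched a symbol in the gene name table and 39458 a chromosome in the annotation of GRCh38.p14, the assembly of hg38. Genes and peaks of the Y chromosome, XIST and TSIX were removed before any total or test. The libraries held 27143754 to 38241899 reverse-strand gene counts. Reads mapped to several places made up 7.9 to 28.97% and ambiguous ones 3.52 to 9.35%; both are left out by the counting, so paralogues and overlapping genes are undercounted to an unknown extent. The 2 libraries of a donor and treatment differed by a chi-square per gene of 4.27 to 7.05 in 7 pairs and 94.78 in the diabetic TGFB1 pair of donor 1, where sampling alone gives about 1, so no library was counted as a copy of another.

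Counts were filtered with filterByExpr, scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit, glmQLFTest), with Benjamini-Hochberg adjustment and a threshold of 0.05. For TGFB1 against untreated, all 16 libraries entered 1 model with donor as a term and a treatment effect per disease group. For diabetic against non-diabetic cells the donor was the replicate: counts were summed per donor and treatment, and the 4 sums of a treatment were compared. The difference of the responses was tested as an interaction on the 8 sums with donor as a term. CPM values are TMM-scaled, and the log2 fold changes come from the fits. Each SE is the absolute log2 fold change divided by the root of its F statistic, and so an approximation. For genes with 0 counts in a group a lower bound of the fold was taken against 3 counts over the group, and for 1 to 3 counts the ratio with a 95% exact interval. DESeq2 1.42.0 and limma 3.58.1 (voom) were run as alternatives.

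The 25 gene lists held 436 genes and were fixed before the data were examined: TGF-beta target genes, collagens and matrix proteins, matrix crosslinking and turnover, mesenchymal markers, epithelial markers, proximal tubule transporters and brush border, gluconeogenesis and fructose metabolism, glycolysis, fatty acid oxidation, tubular injury, NF-kB and inflammatory genes, interferon-stimulated genes, cell cycle, hypoxia, NRF2 and oxidative stress, unfolded protein and integrated stress response, glucose-responsive and polyol pathway, DNA methylation and histone modifiers, and markers of fibroblasts, endothelium, immune cells, podocytes, loop of Henle and distal tubule, collecting duct and urothelium. Lists were tested with limma's camera (preset correlation 0.01, and again with an estimated correlation) and fry, adjusted over the lists of a comparison. Fry was run for a shared direction of change and for change in either direction. Fry tests a list against no change, and camera tests it against the other genes. Where many genes change, most lists therefore pass fry. Lists with fewer than 3 measured members were counted but not tested. The genes named were the 10 raised and 10 lowered protein-coding genes with the largest fold change among called genes with a mean of at least 5 CPM and the same direction in every donor, up to 4 members of each list with the smallest adjusted p, and CCN2, FN1 and COL1A1 as checks of the treatment. Where no gene was called, 20 protein-coding genes with the smallest unadjusted p were named. These had to have a mean of at least 5 CPM and no overlap of donor values between the disease groups. Separation of the donors in these genes is therefore a condition of the choice and not a result. This rule was chosen after the result was seen, as were HAVCR1, HNF4A and CDH1. HLA, immunoglobulin and T cell receptor genes and genes with common deletions were tested and not named.

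Sub-peaks with shared coordinates were counted as 1 peak. Peak numbers were compared with exact permutation tests. All peaks were merged into 184530 regions with an overlap of at least 1 bp; a region was gained in a disease group when both donors had a peak in the treated and none in the untreated list, and lost in the reverse case. Genes raised or lowered by TGFB1 were tested against all other tested genes for a gained region within 10 kb with Fisher's exact test (SciPy 1.17.1, Python 3.11.15), adjusted over 4 tests. Lost regions were tested in the same way, which had not been planned. The annotation gives no strand, so the distance was taken from either end of the gene where the start of transcription had been planned. Overlap between lists was the Jaccard index of base pairs.

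The scripts were tested on simulated counts with 200 changed genes, drawn with the spread and library sizes of the real counts. Means were averaged over the treatments of a donor, or over all donors for the disease comparison, so no other gene changed. In the real TGFB1 comparisons 39.9 and 46.6% of genes were called, so the shares recovered and falsely called need not hold there. For the TGFB1 comparison in non-diabetic cells (18653 genes), 59.7% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 9 false calls among 177. For diabetic against non-diabetic untreated cells (19577 genes), 1.5% were recovered at 2-fold, 44.8% at 4-fold and 97% at 16-fold, with 16 false calls among 111. For the response difference (21393 genes), 17.9% were recovered at 2-fold and 91% at 4-fold, with 24 false calls among 163. The share of false calls lay above the 5% aimed at in each of the 3 comparisons.

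Same-numbered libraries of a disease group come from the same donor, so the replicate numbers pair untreated and treated libraries through the donor. Deviations from the group means of same-numbered libraries correlated across genes with r from 0.488 to 0.695. Within a donor the numbers carried little further pairing, since differences of the 2 libraries correlated between treatments with r from -0.016 to 0.152. The alternatives were the replicate number as a block, no donor term, donor sums, other scaling and filters, other tools, unstranded counts, each library or donor left out, and for peaks a -log10 q of at least 5, lists of equal length, regions at least 50% covered and other distances.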

Results

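RNA and open chromatin were measured in primary human proximal tubule epithelial cells, the cells of the kidney tubule segment that takes back most of the filtered glucose, amino acids and phosphate. The cells came from 2 non-diabetic and 2 diabetic donors and were left untreated or given TGFB1, a cytokine that drives matrix production, for 24 h. RNA sequencing gave 16 libraries, 4 for each disease group and treatment, of which 2 came from each donor. ATAC-seq, in which a transposase inserts adapters into accessible DNA, gave 8 peak lists, 1 per donor and treatment. The RNA libraries held 27143754 to 38241899 gene counts, and 26913 to 28143 genes had a count. The labels do not say whether the 2 libraries of a donor came from separate cultures. The p-values for TGFB1 rest on the spread between these libraries, which may be technical. They also take in the difference of the response between the 2 donors of a disease group. The design asks how the cells responded to TGFB1, and whether cells of diabetic donors, kept in the same medium as the others, differed at rest or in that response.

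The libraries separated first by treatment and then by donor. The first principal component of the log counts (40% of the variance) parted all 8 untreated from all 8 TGFB1-treated libraries, and the second (30.6%) set both treatments of non-diabetic donor 1 apart from the other donors. Across genes, log counts of the 2 libraries of a donor and treatment correlated with r from 0.981 to 0.996, against 0.933 to 0.974 between the donors of a group and 0.928 to 0.965 between the treatments of a donor. Genes are not independent replicates, so these values describe the libraries only. The libraries of donors numbered 1 and 2 also differed in each disease group: ambiguous reads made up 3.52 to 5.4% in the former and 7 to 9.35% in the latter, and mitochondrial counts 0.44 to 0.72% and 0.2 to 0.34%.

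In non-diabetic cells, TGFB1 raised genes of the matrix, of its own signalling pathway and of mesenchymal cells, and lowered transporters and brush border genes of the proximal tubule. COL1A1 (ENSG00000108821, chromosome 17, 50184101 to 50201631 in hg38), the main chain of type I collagen, rose from 20.1 ± 18.0 to 522 ± 196 CPM (normalised counts per 1e6 counts; mean ± SD, n = 4 libraries), a log2 fold change of 5.21 ± 0.43 (SE). FN1, fibronectin, rose from 18300 ± 4320 to 45600 ± 4200 CPM (1.34 ± 0.12), and CCN2, a matricellular growth factor, from 60.1 ± 44.4 to 166 ± 151 CPM (1.14 ± 0.26). LRP2, the endocytic receptor megalin of the brush border, fell from 23.4 ± 26.9 to 0.440 ± 0.447 CPM (-5.59 ± 0.30). Its level before treatment was low in donor 1, at 0.43 and 0.309 CPM, against 41.1 and 51.6 CPM in donor 2. SLC2A2, the basolateral glucose transporter GLUT2, fell from 43.9 ± 16.9 to 0.637 ± 0.192 CPM (-6.04 ± 0.23).

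**Figure D1:**
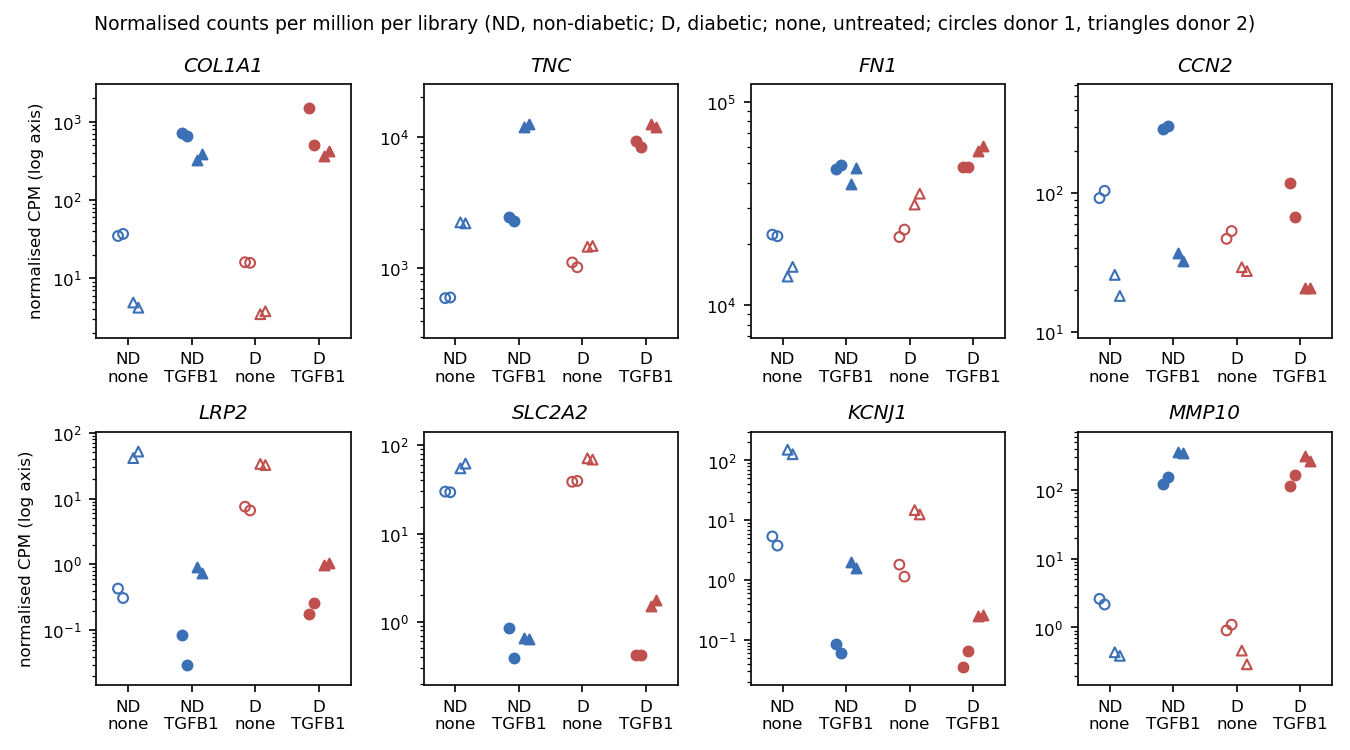
CPM of 8 genes in each RNA library, on log axes, for untreated (open) and TGFB1-treated (filled) cells of non-diabetic (ND, blue) and diabetic (D, red) donors, with circles for donor 1 and triangles for donor 2. COL1A1 lay between 3.47 and 36.8 CPM in the untreated and between 321 and 1490 CPM in the treated libraries.

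Genes were ranked by fold change among called protein-coding genes with a mean of at least 5 CPM and the same direction in both donors. Of the 10 with the largest rise in non-diabetic cells, several were near or at 0 counts before treatment. KANK4, which encodes an ankyrin repeat protein of the cytoskeleton, had no count in the untreated libraries and was at least 1440-fold higher with TGFB1. ISLR2, a leucine-rich repeat membrane protein, was at least 1100-fold higher, and S1PR5, a sphingosine 1-phosphate receptor, at least 622-fold higher, each against a floor of 3 counts over the untreated group. PKP1, a desmosomal plakophilin, was 1880-fold higher (95% counting interval 643 to 9120), FOXS1, a forkhead transcription factor, 1750-fold higher (483 to 14400) and DHRS2, a dehydrogenase, 767-fold higher (212 to 6340). LDLRAD4, an inhibitor of TGF-beta signalling, rose by 7.50 ± 0.35 on the log2 scale, LEFTY1, an antagonist of the TGF-beta family, by 7.43 ± 0.26, the matrix metalloproteinase MMP10 by 7.36 ± 0.62 and SLN, a regulator of the sarcoplasmic calcium pump, by 7.29 ± 0.36. These floors and intervals cover counting error only.

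Within the same limits, a mean of at least 5 CPM among them, the 10 genes with the largest fall in non-diabetic cells were LRP2, SLC2A2 and another 8. TMEM252, a transmembrane protein, fell by 7.08 ± 0.19 on the log2 scale and ADH6, an alcohol dehydrogenase, by 6.99 ± 0.29. HLF, a transcription factor of the PAR bZIP family, fell by 6.28 ± 0.12, from 91.9 ± 59.7 to 1.25 ± 0.98 CPM. KCNJ1, the renal potassium channel ROMK, fell by 6.22 ± 0.20, and SLC17A1, a phosphate and urate transporter, by 6.12 ± 0.17. PDK4, a kinase that shuts off pyruvate dehydrogenase in fasting, fell by 5.30 ± 0.24, SEMA4A, a semaphorin, by 5.10 ± 0.48 and DEPTOR, an inhibitor of mTOR, by 5.04 ± 0.23.

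The gene lists fixed in advance that rose in non-diabetic cells were led by known TGF-beta targets. Of 20 measured targets, 18 rose and 0 fell (18 and 0 adjusted over the list alone). They included TGFBI, a secreted adhesion protein (5.55 ± 0.31), the cell cycle inhibitor CDKN2B (3.03 ± 0.11), LTBP2 of the latent TGF-beta binding proteins (2.76 ± 0.16) and JUNB (2.16 ± 0.14). The camera test of limma gave the list an adjusted p of 2.21e-22. Of 27 collagens and matrix proteins, 18 rose and 2 fell (19 and 4 adjusted over the list alone; adjusted p = 6.58e-13). Tenascin TNC (2.22 ± 0.10), COL4A1 (2.04 ± 0.09) and SPARC (1.97 ± 0.13) were among the first by adjusted p. Of 23 genes of matrix crosslinking and turnover, 19 rose and 1 fell (19 and 1 adjusted over the list alone; adjusted p = 1.16e-11). The gelatinase MMP9 (6.92 ± 0.33) and the collagen prolyl hydroxylases P4HA3 (4.79 ± 0.26) and P4HA2 (2.10 ± 0.13) rose, and the stromelysin MMP3 was 357-fold higher (122 to 1730). Of 18 mesenchymal markers, 16 rose and 0 fell (16 and 1 adjusted over the list alone; adjusted p = 9.08e-17). They included transgelin TAGLN (3.8 ± 0.22), the integrin ITGAV (2.51 ± 0.15), tropomyosin TPM1 (2.18 ± 0.11) and N-cadherin CDH2 (1.66 ± 0.08). Of 18 genes of the unfolded protein and integrated stress response, 14 rose and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 0.000218). The endoplasmic reticulum proteins MANF (0.99 ± 0.09), HSP90B1 (0.84 ± 0.07) and HSPA5 (0.69 ± 0.08) rose, as did the asparagine synthetase ASNS (0.84 ± 0.07). Each of these 5 lists kept its call with an estimated correlation.

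Of 30 cell cycle genes in non-diabetic cells, 23 rose and 0 fell (24 and 0 adjusted over the list alone). They included the proliferation marker MKI67 (1.16 ± 0.21), the spindle proteins TPX2 (1.19 ± 0.22) and BUB1 (1.31 ± 0.25) and survivin BIRC5 (1.52 ± 0.30). The list passed with the preset correlation (camera, adjusted p = 9.01e-05) but not with an estimated one (adjusted p = 0.538). It also passed fry's test for a shared direction, up (adjusted p = 0.00615), which called 19 of the 23 lists tested in these cells. The members that did not pass were CCNE2, MCM2, MCM3, MCM4, MCM5, MCM6 and PCNA, named after their values were seen. MCM7 was among those that rose. Camera called none of the next 4 lists in non-diabetic cells. Fry's test for a shared direction called the histone modifier and glucose-responsive lists, up (adjusted p = 0.00122 and 0.000135). It did not call hypoxia and glycolysis (fry, adjusted p = 0.178 and 0.16). In hypoxia response 8 of 14 were higher and 3 lower (8 and 3 adjusted over the list alone), with the growth factor VEGFA at 1.42 ± 0.18 and the carbonic anhydrase CA12 at -1.57 ± 0.12. In glycolysis 8 of 20 were higher and 3 lower (9 and 4 adjusted over the list alone), with the glucose transporter SLC2A1 at 0.87 ± 0.13. Of the DNA methylation and histone modifiers 12 of 26 were higher and 4 lower (12 and 4 adjusted over the list alone), with the methyltransferase DNMT3B at 1.16 ± 0.10 and the acetyltransferase KAT2B at -1.24 ± 0.12. Of 14 genes of the glucose-responsive and polyol list, 4 rose and 4 fell (5 and 4 adjusted over the list alone). GFPT2 of hexosamine synthesis (4.71 ± 0.20) and the oxidase NOX4 (1.60 ± 0.13) rose, and aldose reductase AKR1B1 (-1.06 ± 0.10) fell.

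Of 25 proximal tubule transporters and brush border genes in non-diabetic cells, 19 fell and 2 rose (19 and 2 adjusted over the list alone; camera adjusted p = 1.32e-07, and 0.0356 with an estimated correlation). Beside LRP2, the amino acid transporter subunit SLC3A1 (-3.31 ± 0.26), the peptidase MME (-1.47 ± 0.12) and the scaffold PDZK1 (-1.38 ± 0.10) fell. HNF4A, a transcription factor that sets proximal tubule identity, was 93.3-fold lower (25.4 to 776). Its level was low before treatment, with 178 counts over the untreated libraries against 2 over the treated ones. Of 23 fatty acid oxidation genes, 16 fell and 1 rose (17 and 1 adjusted over the list alone; camera adjusted p = 4.85e-07, but adjusted p = 0.142 with an estimated correlation). Beside PDK4, the acyl-CoA synthetases ACSM2B (-2.65 ± 0.27) and ACSL1 (-1.85 ± 0.16) and the coactivator PPARGC1A (-2.36 ± 0.16) fell. Of 7 genes of gluconeogenesis and fructose metabolism, 5 fell and 1 rose (5 and 1 adjusted over the list alone). PCK1 (-3.68 ± 0.68), FBP1 (-2.40 ± 0.37) and KHK (-1.46 ± 0.19) were among the lower ones. Of 20 epithelial markers, 8 fell and 4 rose (10 and 4 adjusted over the list alone). The claudin CLDN3 (-1.78 ± 0.17), kidney cadherin CDH16 (-1.27 ± 0.10) and PAX8 (-1.18 ± 0.13) were lower and keratin KRT7 (1.06 ± 0.13) higher, and E-cadherin CDH1 was at -0.03. Of 18 genes of the NRF2 and oxidative stress list, 10 fell and 3 rose (11 and 3 adjusted over the list alone). AKR1B10 (-2.55 ± 0.31), AKR1C1 (-1.38 ± 0.14) and catalase CAT (-1.15 ± 0.11) were lower and heme oxygenase HMOX1 (1.87 ± 0.10) was higher. The gluconeogenesis, epithelial and NRF2 lists were not called by camera. Fry's test for a shared direction called each of them, down (adjusted p = 0.00163, 0.00457 and 6.47e-06), among 19 of 23 lists.

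Injury and immune lists split in non-diabetic cells. Of 16 tubular injury markers, 9 fell and 6 rose (9 and 6 adjusted over the list alone). The doublecortin-domain gene DCDC2 (-1.91 ± 0.23) and CD24 (-1.55 ± 0.19) fell and the urokinase receptor PLAUR (1.78 ± 0.22) rose. HAVCR1, which encodes KIM-1, was also lower (-2.39). Of 25 NF-kB and inflammatory genes, 10 fell and 6 rose (10 and 8 adjusted over the list alone). The acute phase genes SAA2 (-1.45 ± 0.15) and SAA1 (-1.22 ± 0.10) and the chemokine CXCL6 (-1.28 ± 0.15) were lower and the cytokine LIF (1.53 ± 0.18) higher. Its median log2 fold change was 0.20 and its mean -0.31, while camera's direction was down. Of 28 interferon-stimulated genes, 9 fell and 7 rose (9 and 7 adjusted over the list alone). GBP2 (-1.62 ± 0.11), IFIT2 (-1.10 ± 0.17) and IFI35 (-0.95 ± 0.15) were lower. Camera called none of these 3 lists. For change in either direction fry gave adjusted p-values of 4.30e-08, 5.66e-12 and 1.79e-11, but 22 of the 23 lists tested passed. For a shared direction fry gave adjusted p-values of 0.000706, 0.00832 and 0.0201, each down, but 19 of the 23 passed. With 39.9% of all tested genes called in these cells, the fry values do not set these lists apart from other genes.

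Markers of other cell types were also measured in non-diabetic cells, and not all were low. KCNJ1, a marker of the loop of Henle and distal tubule, stood at 151 and 127 CPM in the untreated libraries of donor 2. LRP2 stood at 41.1 and 51.6 CPM in the same libraries. In donor 1 KCNJ1 was at 5.36 and 3.77 CPM and LRP2 at 0.43 and 0.309 CPM. Of 4 loop of Henle and distal tubule markers, 3 fell and 0 rose (3 and 0 adjusted over the list alone; camera adjusted p = 4.13e-11, and 0.000311 with an estimated correlation). They were KCNJ1, the sodium-potassium-chloride cotransporter SLC12A1 (-3.74 ± 0.25, from 117 ± 133 to 7.79 ± 8.78 CPM) and the sodium-chloride cotransporter SLC12A3 (-2.18 ± 0.14). Of 10 fibroblast and myofibroblast markers, 5 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.0181, but adjusted p = 0.0788 with an estimated correlation). Beside COL1A1, FAP (5.47 ± 0.45), PDGFRA (4.84 ± 0.43) and PDGFRB (3.26 ± 0.50) rose to between 1.63 and 4.36 CPM. Of 5 podocyte markers, 2 rose and 1 fell (2 and 1 adjusted over the list alone), with PTPRO at -3.16 ± 0.33, and of 4 collecting duct markers 1 rose and 1 fell (1 and 1 adjusted over the list alone), with ATP6V1B1 at -2.91 ± 0.45; the medians of these lists (0.53 and 0.40) and their means (-0.14 and -0.18) differed in sign. Of 4 urothelial and basal epithelial markers, 2 rose and 1 fell (2 and 1 adjusted over the list alone), with TP63 at 2.18 ± 0.31. Of 2 endothelial markers 1 rose and 1 fell (1 and 1 adjusted over the list alone), as did the 2 immune cell markers (1 and 1 adjusted over the list alone), with CSF1R at 4.38 ± 0.48 and CD14 at -3.76 ± 0.30. The calls of SYNPO, AQP3, TEK and CDH5 in these lists were lost when some libraries were left out. AQP3, at 1.38 ± 0.45, was at -0.27 in donor 1 alone, and SYNPO, at 1.04 ± 0.39, was at -0.08 in donor 2 alone.

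In total, 7583 of 18996 tested genes passed an adjusted p of 0.05 in non-diabetic cells (edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, donor as a term), 3528 higher and 4055 lower, and 3082 of them changed by at least 2-fold. Of the called genes, 98.6% changed in the called direction in donor 1 and 99.5% in donor 2. With no donor term 3718 genes passed, and with counts summed per donor and treatment 2832.

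In diabetic cells, TGFB1 raised TGF-beta target, matrix and mesenchymal genes and lowered transporters and brush border genes of the proximal tubule. COL1A1 went from 9.74 ± 7.07 to 696 ± 534 CPM (mean ± SD, n = 4 libraries; log2 fold change 6.35 ± 0.44) and FN1 from 27900 ± 6430 to 53300 ± 6780 CPM (0.96 ± 0.12). CCN2 did not pass the test, at 39.3 ± 12.8 and 56.7 ± 46.2 CPM (0.24 ± 0.26, adjusted p = 0.483 by edgeR), and without the TGFB1 replicate 1 library its log2 fold change was -0.07. That library also held the highest COL1A1 level, 1490 CPM against 501 CPM in the other library of the donor. LRP2 fell by 5.01 ± 0.24 on the log2 scale and SLC2A2 from 54.4 ± 17.9 to 1.04 ± 0.72 CPM (-5.79 ± 0.22).

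Genes were ranked as before, among called protein-coding genes with a mean of at least 5 CPM and the same direction in both donors. The 10 with the largest rise in diabetic cells shared KANK4, ISLR2, S1PR5, PKP1, FOXS1, DHRS2 and LDLRAD4 with the non-diabetic ones. KANK4 again had no count before treatment and was at least 2300-fold higher, against a floor of 3 counts over the group. ISLR2 was 2550-fold higher (95% counting interval 873 to 12400), DHRS2 1650-fold (457 to 13700) and S1PR5 1250-fold (346 to 10300). The other genes were TSPAN2, a tetraspanin (9.97 ± 0.70), the cytokine IL11 (9.51 ± 0.90), which went from 0.450 ± 0.067 to 344 ± 151 CPM, and STRA6, the cellular receptor for retinol uptake (8.58 ± 0.97); PKP1 (8.53 ± 0.29), FOXS1 (8.57 ± 0.31) and LDLRAD4 (8.59 ± 0.33) had more than 3 counts before treatment. Within the same limits the largest falls were in TMEM252 (-6.48 ± 0.16), SLC17A1 (-6.31 ± 0.17), HLF (-6.11 ± 0.12), SLC2A2 and the adhesion receptor ADGRF1 (-5.03 ± 0.47). Next came LRP2, the growth factor GDF5 (-4.88 ± 0.16), the protease TMPRSS4 (-4.82 ± 0.66), PDK4 (-4.76 ± 0.28) and SLC27A2, a fatty acid transporter (-4.69 ± 0.47).

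Of 20 TGF-beta targets in diabetic cells, 17 rose and 1 fell (17 and 1 adjusted over the list alone; camera adjusted p = 4.63e-20). They included LTBP2 (3.38 ± 0.16), CDKN2B (2.94 ± 0.11), the SMAD corepressor SKIL (2.77 ± 0.15) and the transcription factor BHLHE40 (2.46 ± 0.12). Of 27 collagens and matrix proteins, 17 rose and 5 fell (19 and 5 adjusted over the list alone; adjusted p = 1.45e-10). TNC (3.06 ± 0.11), SPARC (2.11 ± 0.13) and COL4A1 (1.72 ± 0.09) were higher. Of 23 genes of matrix crosslinking and turnover, 18 rose and 1 fell (19 and 1 adjusted over the list alone; adjusted p = 6.09e-13). MMP3 (7.41 ± 0.39), MMP9 (4.78 ± 0.31), P4HA3 (4.78 ± 0.25) and P4HA2 (2.19 ± 0.13) rose. Of 18 mesenchymal markers, 16 rose and 0 fell (16 and 0 adjusted over the list alone; adjusted p = 2.06e-13). They included the transcription factor SNAI1 (5.76 ± 0.32), the cadherins CDH11 (4.81 ± 0.25) and CDH2 (1.43 ± 0.08) and ITGAV (2.70 ± 0.15). Of 18 genes of the unfolded protein and integrated stress response, 13 rose and 3 fell (14 and 3 adjusted over the list alone; adjusted p = 0.00193). They included the stress-induced mTOR inhibitor DDIT4 (1.5 ± 0.10), HSPA5 (1.02 ± 0.08), HSP90B1 (0.92 ± 0.07) and MANF (0.89 ± 0.09). Of 10 fibroblast and myofibroblast markers, 5 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.00908). PDGFRA (5.12 ± 0.35), FAP (4.24 ± 0.38) and PDGFRB (2.88 ± 0.37) rose to between 4.16 and 7.92 CPM. These 6 lists kept their calls with an estimated correlation.

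Further lists in diabetic cells passed with camera's preset correlation and not with an estimated one. Of 14 hypoxia response genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.000367, but adjusted p = 0.364 with an estimated correlation). The members included VEGFA (2.22 ± 0.18), SLC2A1 (1.58 ± 0.13), P4HA1 (1.51 ± 0.14) and the histone demethylase KDM3A (1.04 ± 0.09). Of 20 glycolysis genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 0.00247, but adjusted p = 0.375 with an estimated correlation). The members included PFKFB4 (1.86 ± 0.25) and lactate dehydrogenase LDHA (1.01 ± 0.14). Of 30 cell cycle genes, 21 rose and 2 fell (22 and 2 adjusted over the list alone; adjusted p = 0.00411, but adjusted p = 0.515 with an estimated correlation). TPX2 (1.37 ± 0.21), MKI67 (1.36 ± 0.21) and FOXM1 (1.3 ± 0.22) were higher and the replication gene MCM6 (-0.45 ± 0.07) lower. Of 14 genes of the glucose-responsive and polyol list, 7 rose and 4 fell (7 and 4 adjusted over the list alone; adjusted p = 0.0195, but adjusted p = 0.0567 with an estimated correlation). The members included GFPT2 (4.16 ± 0.13), NOX4 (1.52 ± 0.13) and AKR1B1 (-1.26 ± 0.10). Of 26 DNA methylation and histone modifiers, 14 rose and 3 fell (14 and 3 adjusted over the list alone; adjusted p = 0.0315, but adjusted p = 0.234 with an estimated correlation). The members included DNMT3B (1.13 ± 0.10), the demethylase TET1 (0.85 ± 0.12), KAT2B (-1.12 ± 0.12) and the deacetylase HDAC9 (-2.29 ± 0.28).

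Of 25 proximal tubule transporters and brush border genes in diabetic cells, 20 fell and 2 rose (20 and 2 adjusted over the list alone; camera adjusted p = 4.46e-09, and 0.0098 with an estimated correlation). SLC3A1 (-4.51 ± 0.27) and PDZK1 (-2.05 ± 0.10) were lower and the amino acid transporter SLC7A7 (2.37 ± 0.17) higher. Of 23 fatty acid oxidation genes, 18 fell and 0 rose (19 and 1 adjusted over the list alone; adjusted p = 1.13e-07, but adjusted p = 0.0599 with an estimated correlation). The members included ACSM2B (-2.74 ± 0.22), PPARGC1A (-2.06 ± 0.15) and ACSL1 (-2.01 ± 0.16). Of 25 NF-kB and inflammatory genes, 13 fell and 3 rose (15 and 3 adjusted over the list alone; adjusted p = 0.0334, but adjusted p = 0.364 with an estimated correlation). The apoptosis inhibitor BIRC3 (-4.37 ± 0.41) and the chemokine CXCL2 (-3.59 ± 0.31) were lower and LIF (1.61 ± 0.18) higher. Of 4 loop of Henle and distal tubule markers, 3 fell and 0 rose (3 and 0 adjusted over the list alone; adjusted p = 4.68e-05, and 0.00871 with an estimated correlation). KCNJ1 (-5.57 ± 0.25) and SLC12A1 (-3.63 ± 0.26) fell.

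Camera did not call the remaining lists in diabetic cells. Fry's test for a shared direction called 21 of the 23 lists tested in these cells. Of 20 epithelial markers, 11 were lower and 4 higher (12 and 4 adjusted over the list alone), with the splicing regulator ESRP2 at -3.08 ± 0.38. Of 7 genes of gluconeogenesis and fructose metabolism, 4 were lower and 2 higher (4 and 2 adjusted over the list alone), with PCK1 at -4.31 ± 0.82. Of 18 genes of the NRF2 and oxidative stress list, 9 were lower and 3 higher (9 and 5 adjusted over the list alone), with AKR1B10 at -2.43 ± 0.25 and HMOX1 at 1.70 ± 0.10. Of 16 tubular injury markers, 9 were lower and 6 higher (9 and 6 adjusted over the list alone), with DCDC2 at -2.91 ± 0.23, HAVCR1 at -2.93 and the hyaluronan receptor CD44 at 1.27 ± 0.11. Of 28 interferon-stimulated genes, 11 were lower and 6 higher (12 and 6 adjusted over the list alone), with IFIT2 at -1.62 ± 0.18. Of 5 podocyte markers 2 were higher and 2 lower (2 and 2 adjusted over the list alone), with a median of 0.59, a mean of 0.10 and camera's direction down. Of 4 collecting duct markers 2 were higher and 0 lower (2 and 0 adjusted over the list alone), and of 4 urothelial and basal epithelial markers 2 and 1 (2 and 1 adjusted over the list alone). Of 2 endothelial markers 1 was higher and 0 lower (1 and 0 adjusted over the list alone), and of 2 immune cell markers 1 and 1 (1 and 1 adjusted over the list alone). AQP3 rose to 21.7 ± 4.5 CPM, CSF1R from 0.0822 ± 0.0392 to 6.17 ± 0.20 CPM, and TP63 was 12.1-fold higher on 2 counts against 19 (2.92 to 107).

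**Figure D2:**
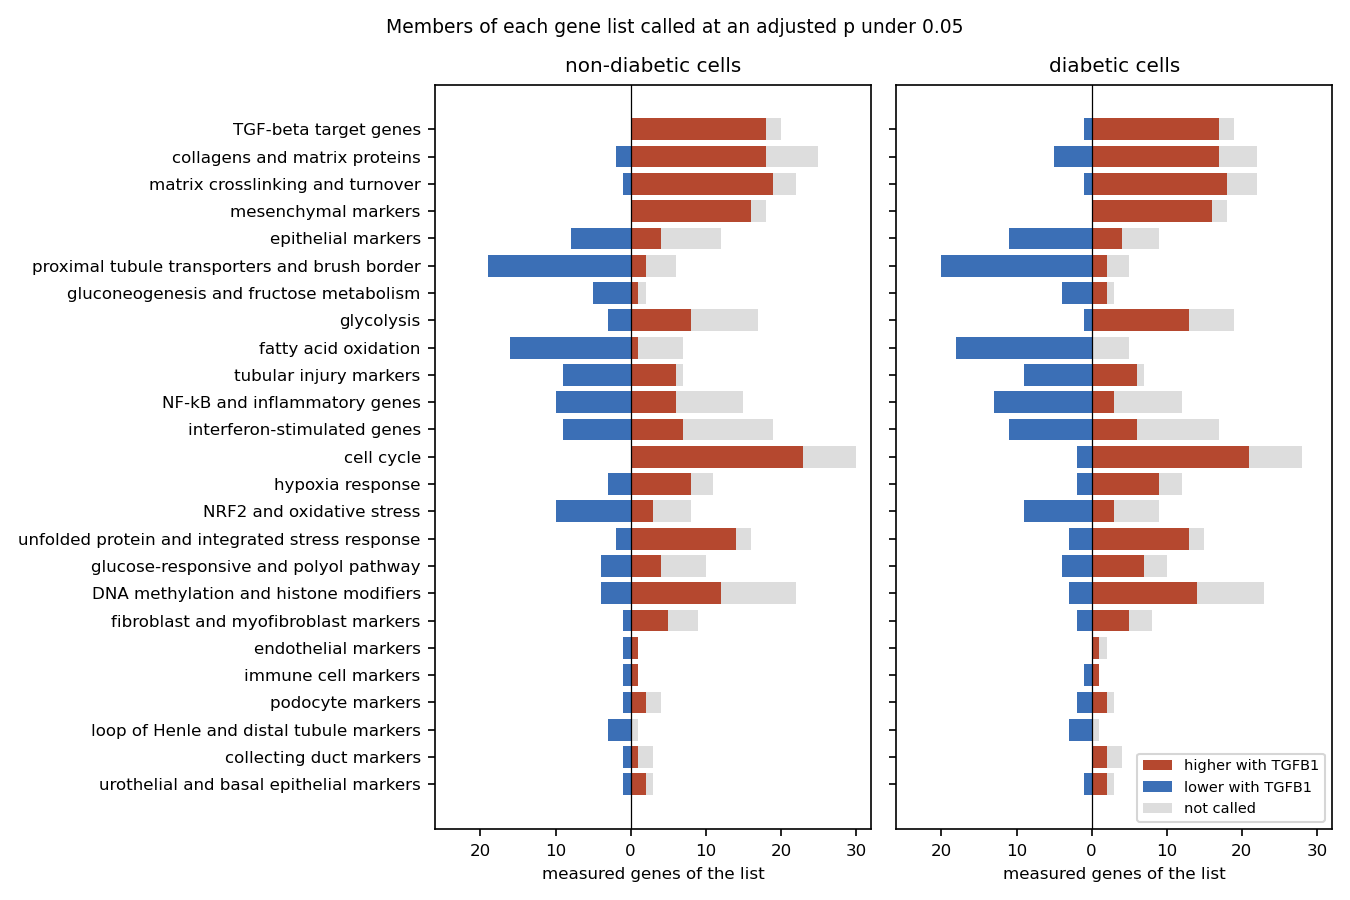
Number of measured members of each of 25 gene lists that were higher (red, to the right), lower (blue, to the left) or not called (grey) with TGFB1 at an adjusted p of 0.05, in non-diabetic (left) and diabetic (right) cells. Of 20 TGF-beta targets, 18 were higher in non-diabetic and 17 in diabetic cells, and of 25 proximal tubule genes, 19 and 20 were lower.

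In diabetic cells 8860 of 18996 genes passed the same test, 4125 higher and 4735 lower, and 3556 changed by at least 2-fold; 99.8% of the called genes changed in the called direction in each donor. With no donor term 4679 genes passed, with counts summed per donor 4002, and in donor 1 alone 3310, where the TGFB1 replicate 1 library stood apart from its partner. Without that library 10370 genes passed.

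The responses of the disease groups resembled each other gene by gene. Of the genes tested, 2820 were raised in both groups and 3257 lowered in both, where independent lists of these lengths would share 766 and 1011, and 47 were called in opposite directions. The log2 fold changes of all 18996 genes correlated across genes with r = 0.888 and rho = 0.796, and 93.7% of the 10319 genes called in either group had the same sign in both. The shared calls were 1505 and 1455 without the donor term, 1183 and 1132 with donor sums, 1244 and 1140 in donors numbered 1 alone and 4320 and 4212 in donors numbered 2 alone. In donors numbered 1 alone r was 0.736, and without a low-count filter it was 0.521. Genes called in opposite directions numbered 3 without the donor term, 0 with donor sums, and 111 and 148 in donors numbered 1 and 2 alone. Genes are not independent replicates, and the groups shared 1 estimate of the spread.

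**Figure D3:**
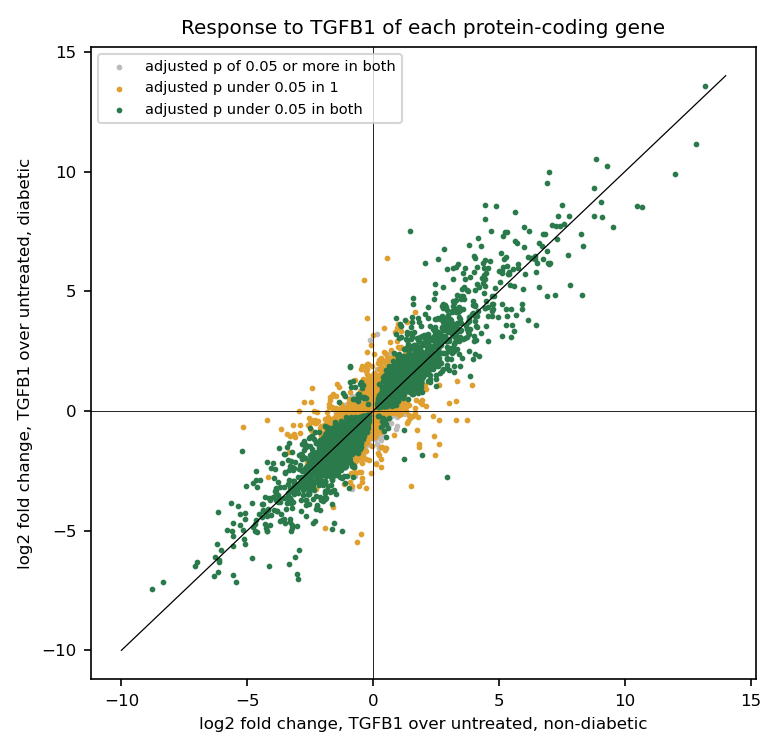
Log2 fold change with TGFB1 of each protein-coding gene in non-diabetic (horizontal axis) and diabetic (vertical axis) cells, coloured by whether the adjusted p was under 0.05 in both groups (green), in 1 (orange) or in neither (grey), with the line of equal response in black. Over all tested genes the values correlated with r = 0.888.

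Untreated cells of diabetic and non-diabetic donors were compared to ask whether the groups differed at rest, and no gene passed the test. Nearest genes were taken only from those whose donor values did not overlap between the groups, as in 25% of all tested genes. The 20 such protein-coding genes that came nearest were, with the exception of PGM5, lower in diabetic cells. They included the protocadherin PCDH1 (36.9 ± 9.46 CPM in non-diabetic and 6.09 ± 0.45 in diabetic cells; SD over n = 2 donors), the epithelial integrin ITGB6 (277 ± 69.8 and 63.3 ± 7.85), the mucin MUC1 (32.5 ± 13.9 and 3.28 ± 1.5), the adhesion molecule L1CAM (241 ± 129 and 25.4 ± 9.95) and the transcription factor SIM1 (42.3 ± 5.25 and 12.5 ± 0.11). Others were MAL, a protein of apical transport (120 ± 69.6 and 15.7 ± 2.11), PIGR, the receptor that carries immunoglobulin across epithelia (22.2 ± 0.46 and 3.75 ± 1.51), IGFBP2 (36.7 ± 0.29 and 9.57 ± 1.98), FGFR2 (9.02 ± 2.67 and 1.52 ± 0.07), S100A2 (41.6 ± 4.77 and 12.5 ± 1.37) and LIPH (45.0 ± 4.79 and 7.44 ± 2.11). PGM5, a phosphoglucomutase-related protein of adherens junctions, was at 1.17 ± 0.33 CPM in non-diabetic and 43.0 ± 26.4 in diabetic cells. FN1 (18300 ± 5230 and 27900 ± 7540), COL1A1 (20.1 ± 22 and 9.74 ± 8.65) and CCN2 (60.1 ± 53.9 and 39.3 ± 15.3) had adjusted p-values of 1 by edgeR.

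No member of the 25 gene lists passed in the untreated comparison, and adjusted over the list alone 1 did, the interferon-stimulated gene IFI44L (38.8 ± 8.12 CPM in non-diabetic and 12.5 ± 0.36 in diabetic cells). With camera's preset correlation 8 lists passed: in diabetic cells the epithelial markers (median log2 difference -0.90), NF-kB and inflammatory genes (-1.35), interferon-stimulated genes (-0.98), endothelial markers (-2.36) and loop of Henle and distal tubule markers (-3.05) were lower, and the proximal tubule (0.34), glycolysis (0.18) and cell cycle (0.53) lists higher. None of the 8 passed otherwise (adjusted p = 0.735 with an estimated correlation for 7 of them and 0.744 for glycolysis), and fry called 0 lists, with adjusted p-values of 0.754 or more. The medians and means of the mesenchymal (0.23 and -0.12), fatty acid oxidation (0.18 and -0.04) and collecting duct (0.17 and -0.35) lists differed in sign, and for the matrix crosslinking and fibroblast lists camera's direction was up while median and mean were negative.

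The edgeR quasi-likelihood test on 4 donor sums called 0 of 20252 genes, with 763 at an unadjusted p under 0.05 where chance alone gives 1013, and a smallest adjusted p of 0.932. DESeq2 called 244 genes and limma-voom with donor as a random effect 76. The biological coefficient of variation between donors was 0.406. Without non-diabetic donor 2 430 genes passed, and with each library taken as an independent sample 494.

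Among TGFB1-treated cells no gene passed between the disease groups either. Nearest genes were again taken only from those without overlap of donor values, as in 25.8% of all tested genes. The genes nearest to the threshold were mostly lower in diabetic cells: P-cadherin CDH3 (239 ± 49.4 CPM in non-diabetic and 21.1 ± 16.1 in diabetic cells; SD over n = 2 donors), the epithelial transcription factor TFCP2L1 (72.0 ± 9 and 16.1 ± 6.90), the collagen COL11A1 (51.3 ± 7.93 and 16.1 ± 2.03), the growth factors FGF2 (168 ± 11.7 and 73.5 ± 0.51) and GDF15 (35.9 ± 4.45 and 14.9 ± 0.66), the phosphodiesterase PDE4D (88.6 ± 11.2 and 26.6 ± 3.98) and the glycoprotein GPNMB (85.6 ± 9.46 and 25.3 ± 8.74). Higher in diabetic cells were the lipid droplet protein PLIN2 (29.3 ± 1.77 and 66.9 ± 10.7), TM4SF18 (8.22 ± 0.04 and 25.6 ± 6.90), LY75 (2.12 ± 0.73 and 9.12 ± 0.64) and IGFN1 (2.25 ± 0.05 and 17.5 ± 9.76). LIPH, IGFBP2 and PDLIM4 were among the nearest genes in both comparisons, at 28.6 ± 18.8 and 3.29 ± 0.003 CPM for LIPH here. COL1A1 stood at 522 ± 235 CPM in non-diabetic and 696 ± 425 in diabetic cells, FN1 at 45600 ± 3270 and 53300 ± 8130 and CCN2 at 166 ± 185 and 56.7 ± 50.6.

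No list member passed in treated cells, and adjusted over the list alone 1 did, TP63, which stood at 1.46 ± 0.85 CPM in the non-diabetic and 0.156 ± 0.072 in the diabetic libraries (SD, n = 4 libraries). Camera's preset correlation called 11 lists: lower in diabetic cells were the epithelial (median -2.10), tubular injury (-0.31), NF-kB (-2.43), interferon (-1.15), loop of Henle (-2.90) and urothelial (-3.22) lists, and higher were the proximal tubule (0.48), glycolysis (0.48), cell cycle (0.30), hypoxia (0.57) and glucose-responsive (0.19) lists. None passed otherwise (adjusted p = 0.567 with an estimated correlation for 10 of them and 0.605 for the cell cycle), and fry called 0, with a smallest adjusted p of 0.0655. The medians and means of the mesenchymal (0.32 and -0.30), fatty acid oxidation (0.03 and -0.15) and endothelial (0.14 and -0.74) lists differed in sign, and for matrix crosslinking camera's direction was up while both were negative. The edgeR test called 0 of 20095 genes, with 650 at an unadjusted p under 0.05 where chance gives 1005; DESeq2 called 144 and limma-voom 28. Without non-diabetic donor 2 711 genes passed, without non-diabetic donor 1 3, and with the libraries as independent samples 427.

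The log2 differences between disease groups in untreated and in treated cells correlated across 19070 genes with r = 0.743 and rho = 0.555. The same donors entered both comparisons, so part of that correlation may come from the donors rather than the disease groups.

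The difference of the TGFB1 response between the disease groups was tested as an interaction on the donor sums, and no gene passed. Nearest genes were taken only from those whose donor responses did not overlap between the groups, as in 29.8% of all tested genes. The nearest was SLC7A8, an amino acid transporter, whose log2 fold changes with TGFB1 were 1.94 and 1.96 in the diabetic donors and -0.11 and -0.30 in the non-diabetic donors. PCDH1 responded by 3.89 and 3.67 against 0.89 and 1.68, SORL1, a sorting receptor, by 1.89 and 1.76 against -1.54 and -0.28, and the adhesion molecule NECTIN4 by 3.13 and 3.22 against 0.81 and 1.53. FOXQ1, a forkhead transcription factor, was at -2.59 and -3.01 against -0.11 and -0.79, KRT80 at -2.26 and -2.96 against -0.08 and -0.91, and ALDOC, an aldolase, at 1.46 and 0.92 against -0.64 and -0.34. The ephrin receptor EPHA4 was at 0.19 and 0.10 against -1.04 and -1.06, the scaffold AKAP12 at -0.03 and 0.02 against 1.56 and 1.09, and the prostaglandin receptor PTGFR at 0.81 and 1.28 against -0.49 and -0.35. COL1A1 responded by 5.76 and 6.74 against 4.27 and 6.27, and CCN2 by 0.83 and -0.44 against 1.60 and 0.69.

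For the response difference, no list member passed, over all genes or adjusted over the list alone. The hypoxia (median difference 0.57), glycolysis (0.33), collecting duct (1.17) and endothelial (1.47) lists were higher and the NF-kB list (-0.59) lower by camera's preset correlation, and none of these 5 passed otherwise (adjusted p = 0.792 with an estimated correlation). The medians and means of the tubular injury (0.01 and -0.10) and podocyte (-0.05 and 0.21) lists differed in sign. The edgeR test called 0 of 21897 genes, with 670 at an unadjusted p under 0.05 where chance gives 1095, DESeq2 called 20, and fry called 0 lists. With the 16 libraries as samples and donor as a term 251 genes passed, and with the replicate numbers as a block 70. Without the diabetic TGFB1 replicate 1 library the 251 became 914.

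Chromatin accessibility was compared to see where DNA opened or closed with TGFB1. Every donor had more ATAC-seq peaks after TGFB1 than before it. The peak lists of the non-diabetic donors went from 18968 and 43420 peaks to 72125 and 76220, and those of the diabetic donors from 60489 and 35260 to 83762 and 70504, so the mean over 4 donors rose 1.91-fold (range over donors 1.38 to 3.8). An exact sign-flip permutation test over the 4 donors gave a two-sided p of 0.13, the smallest that 4 donors allow. Untreated diabetic lists held 1.53 times the peaks of non-diabetic ones (exact permutation p = 0.667, n = 2 donors per group) and treated lists 1.04 times (exact permutation p = 1), where the smallest possible p was 0.333. In treated cells the other measures ran the other way: diabetic lists held 0.823 times the peaks with a -log10 q of at least 5 and covered 0.817 times the base pairs (exact permutation p = 0.333 for each). The depth of the ATAC-seq libraries is unknown, since the lists hold no read counts.

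**Figure D4:**
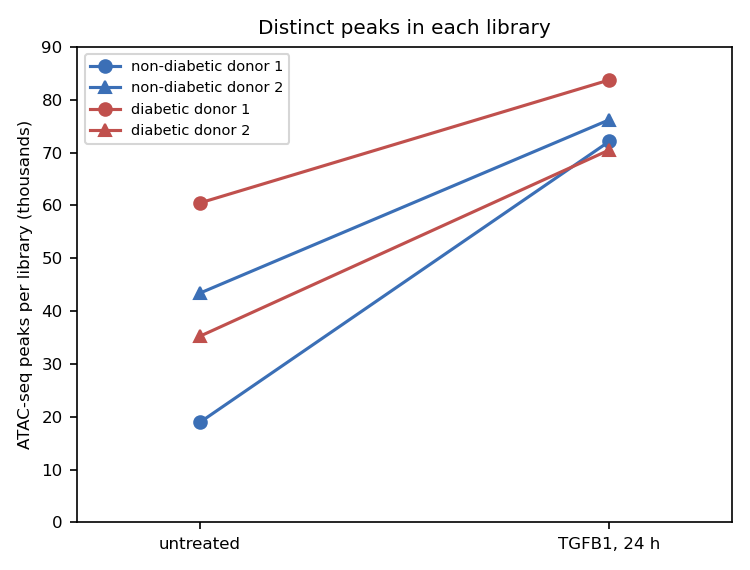
Number of distinct ATAC-seq peaks (vertical axis, in units of 1e3) in the untreated and the TGFB1-treated library of each donor; lines join the libraries of a donor, blue for non-diabetic and red for diabetic, with circles for donor 1 and triangles for donor 2. All 4 lines go up.

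The 8 lists merged into 184530 regions. In both non-diabetic donors 17889 regions were gained with TGFB1 (a peak in the treated list and none in the untreated one) and 185 lost, and in both diabetic donors 10635 were gained and 1205 lost. Independent lists would share 14422 gained and 332 lost regions in the non-diabetic and 11018 and 1388 in the diabetic donors, so of these counts only the gained regions of non-diabetic donors lay above that. Another 2323 regions in non-diabetic and 3714 in diabetic cells were gained in 1 donor and lost in the other. In all 4 donors 4066 regions were gained and 14 lost, where independent lists would share 1031 and 1. The deposited lists differ in length by up to 4.42-fold, and a longer list gains regions by its length alone. With the 18968 strongest peaks of each list, 2996 regions were gained and 1270 lost in non-diabetic cells, against 1570 and 1451 for independent lists. In diabetic cells these were 2543 and 1819, against 1357 and 1330, and in all 4 donors 690 and 181, against 161 and 49. No count test across regions was possible from peak lists.

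Regions gained in all 4 donors lay beside several of the named genes (hg38, fold enrichment over the local background in the treated lists). A region of 465 bp at chromosome 1, 62325569 to 62326033, lay 6134 bp outside KANK4 (6.25 to 7.36-fold). Within DHRS2 a region at chromosome 14, 23638709 to 23639094, was gained (5.94 to 8.54-fold), and outside LDLRAD4 1 at chromosome 18, 13216181 to 13216563 (2.68 to 5.25-fold). TPM1 was overlapped at 1 of its ends by a region at chromosome 15, 63042342 to 63042812 (2.91 to 4.49-fold). Others lay within 10 kb of an end of FOXS1, STRA6, CDKN2B, BHLHE40, COL4A1, PLAUR, CD44, AQP3, TEK and SLC7A7. Gained regions also lay beside genes whose RNA fell, CD14 and CXCL6 among them: SLC2A2 held 1 at chromosome 3, 170999785 to 171000113 (4.03 to 5.86-fold), and PDZK1 1 at chromosome 1, 145706393 to 145706620 (3.02 to 3.88-fold). The annotation used gives gene ends without strand, so the start of transcription, exons and introns were not assigned.

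Gained regions lay beside genes that TGFB1 raised more often than beside other genes. In non-diabetic cells 38.1% of raised genes had a gained region within 10 kb of an end of the gene, against 28.4% of the other genes (odds ratio 1.55, Fisher's exact test, adjusted p = 2.55e-26), and in diabetic cells 22.7% against 15.5% (odds ratio 1.61, adjusted p = 5.92e-24). For lowered genes the odds ratios were 1.09 (adjusted p = 0.0487) and 1.05 (adjusted p = 0.307). Regions lost with TGFB1 lay more often beside lowered genes, with odds ratios of 2.01 (adjusted p = 0.019) in non-diabetic and 1.72 (adjusted p = 6.2e-06) in diabetic cells. With lists of equal length lowered genes passed in both groups (odds ratios 1.36 and 1.3, adjusted p = 0.00164 for each). In non-diabetic cells the call from the deposited lists was lost within 2 kb (odds ratio 1.34, adjusted p = 0.706), within 50 kb (1.29, adjusted p = 0.128) and for regions at least 50% covered (2.02, adjusted p = 0.0742). At a -log10 q of at least 5, where 27 and 408 lost regions were left, neither group had a call (odds ratios 0 and 1.11, adjusted p = 0.819 for both). The tests took 16922 genes with coordinates, and genes are not independent. For gained regions, the call for lowered genes in non-diabetic cells was lost within 2 kb (odds ratio 1.02) and with lists of equal length (0.999). It was kept within 50 kb (1.16) and 10 kb from the gene body (1.35). In diabetic cells lowered genes passed within 50 kb (1.12) and 10 kb from the gene body (1.26).

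Between disease groups, 4519 regions had a peak in both untreated diabetic donors and in neither non-diabetic donor, and 475 the reverse, 4994 in all. Parting the same 4 donors by donor number gave 1819 regions and the crossed parting 6980, so the disease parting was not the one with most regions. In treated cells 3718 regions were in diabetic donors only and 4738 in non-diabetic donors only, 8456 in all, against 5173 and 5246 for the other partings. With lists of equal length the disease parting gave 2870 regions in untreated cells (1797 and 2282 for the others) and 3042 in treated cells (1654 and 1709 for the others). With 3 partings of 4 donors, no test could reach a p of 0.05.

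Peak lists shared a median of 0.319 of their base pairs within a group (Jaccard index, range 0.2 to 0.408 over 4 pairs). Lists of the same treatment and the other disease group shared 0.331 (0.163 to 0.365 over 8 pairs), and the untreated and treated lists of a donor 0.254 (0.133 to 0.319 over 4 pairs). With lists of equal length the medians were 0.397 within a group and 0.389 across disease groups. In treated cells the equal-length lists shared 0.476 within the non-diabetic and 0.446 within the diabetic group, and 0.408 to 0.426 across the groups. In untreated cells they shared 0.267 and 0.348 within the groups and 0.25 to 0.371 across them.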

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

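The tests of a composition bias and of a mislabelled library were chosen after the result was seen, and the test of library depth before it.

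In diabetic cells treated with TGFB1, COL1A1 stood at 1490 CPM in the library of replicate 1 and at 501, 368 and 422 CPM in the others. A value was singled out when its gap to the nearest of 4 libraries, as a share of their range, passed 0.83, a bound that 4 values from 1 normal distribution pass about 1 time in 20. COL1A1 reached 0.882, and in the same group ISLR2 reached 0.831 and PDK4 0.864. STRA6 reached 0.879 among untreated diabetic libraries, where it was at 0.0953 CPM in donor 1 and 0.0543 CPM in donor 2. These were 4 of 113 gene-by-group values. The rate of 1 in 20 does not hold for them, since the 4 libraries of a group are 2 alike libraries from each of 2 donors. The number that chance would give is therefore unknown. Of 28 library measures by group, 2 passed: the share of multimapping reads in diabetic TGFB1 libraries (0.846; 28.97% in replicate 1) and the number of genes detected in the same group (0.945; 27695 in replicate 3 against 27333 to 27353). The forward strand, which no comparison used, held a median of 4.96% of the stranded counts. Of the 139 genes picked by the naming rules in the 2 TGFB1 comparisons, which leave out those named for the response difference, 0 responded in 1 direction in both diabetic donors and in the other direction in both non-diabetic donors.

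The diabetic TGFB1 library of replicate 1 differed from the other library of its donor by a chi-square per gene of 94.78, where the other 7 pairs were at 4.27 to 7.05. A composition bias along the genome, such as 1 tied to GC content, could have this effect: genes of chromosome 19, which is rich in GC, were higher than genes of chromosomes 4 and 13 by a median log2 difference of 0.885, against at most 0.071 in the other pairs (725 and 646 genes). Library depth is excluded as the cause, since at equal depth the chi-square was 86.78 and at most 5.98 in the other pairs. A mix-up with untreated cells or with the other diabetic donor would give a high correlation across genes with their differences, and the higher of these was 0.083 (11565 genes). Gene sequences were not at hand, so GC content itself was not tested, and a biological difference between cultures is not excluded.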

How the results depend on the processing

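Calls for TGFB1 leaned on the donor term, and disease calls on the tool and donors chosen; the cause was not tested except where noted. In non-diabetic cells 3082 genes also changed 2-fold, 3718 passed without the donor term and 2832 with donor sums, where fewer samples enter; other settings gave 5270 to 10718, and leaving out 1 library 6413 to 7292. In diabetic cells the same settings gave 3556, 4679 and 4002, donor 1 alone 3310, the others 6191 to 11029, and leaving out 1 library 7840 to 10370. Replicate numbers as a block gave 6631 and 7933 genes; among the 110 genes named per group this block ended the calls of AQP3 and SYNPO in non-diabetic and KRT17 in diabetic cells, and it changed no other call among them.

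For untreated diabetic against non-diabetic cells, where 0 genes passed, 494 passed with libraries as separate samples, 76 with limma-voom, 244 with DESeq2, 24 without a low-count filter and 859 with the replicate numbers as a block, and leaving out 1 library or donor gave 0 to 430. For treated cells these were 427, 28, 144, 0 and 174, with 0 to 711 on leaving 1 out (3 without non-diabetic donor 1). For the response difference 251 genes passed with 16 libraries, 914 without the diabetic TGFB1 replicate 1 library, 70 with the replicate numbers as a block, 74 without a filter and 20 with DESeq2, and leaving out 1 library or donor gave 0 to 869 (28 without non-diabetic donor 1). The donor number as a block, run for the 2 disease comparisons, left both at 0 genes. Without a donor, 1 group has a single sum and the spread comes from the other group alone.

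AQP3 in non-diabetic cells turned to -0.27 in donor 1 alone and SYNPO to -0.08 in donor 2 alone. CCN2 in diabetic cells lay between -0.07, without the TGFB1 replicate 1 library, and 0.41 on leaving out 1 library, and was at -0.42 in donor 2 alone (edgeR, adjusted p = 4.13e-05). Of 116 list tests 49 passed with the preset correlation and 15 with an estimated one. With fry 40 passed for a shared direction and 44 for change in either direction.

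The ratio of peak numbers stayed between 1.66 and 2.47. Regions gained in all 4 donors went from 4066 to 690 with lists of equal length and to between 5447 and 8741 on leaving out 1 donor (6568 and 6484 without the second donors), where fewer donors must share a region. Regions in 1 disease group only, 4994 untreated and 8456 treated, were 2013 and 4930 at a -log10 q of at least 5, 2870 and 3042 with equal lengths, and 3257 and 11353 at least 50% covered; with 1 donor left out they were 16157 to 31445 and 29695 to 38883. Odds ratios for raised genes stayed between 1.37 and 1.97. For lowered genes in non-diabetic cells the call was lost within 2 kb (1.02), with equal lengths (0.999), at least 50% covered (1.06) and at a -log10 q of at least 5 (0.985). It was kept within 50 kb (1.16) and 10 kb from the gene body (1.35). With 1 donor left out the odds ratios were 1.27 and 1.32. In diabetic cells lowered genes passed within 50 kb (1.12), 10 kb from the gene body (1.26) and with 1 donor left out (1.13 to 1.14). Medians of list overlap within a group stayed between 0.304 and 0.397. Peak lists carry no read depth, so depth as a limit on peaks was not tested.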

Other observations

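The test of longer peak lists and the splits without a donor term were chosen after the result was seen, and the other tests below before it.

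In untreated cells 6 genes, picked after their values were seen, differed between the donors of a disease group. SLC12A1, the cotransporter of the thick ascending limb, stood at 2.51 and 232 CPM in non-diabetic donors 1 and 2 and at 2.5 and 29.7 CPM in diabetic donors 1 and 2, and the potassium channel KCNJ1 at 4.56, 139, 1.48 and 13.6 CPM. SLC12A3 of the distal convoluted tubule ran the other way, at 24.4, 4.01, 1.42 and 0.365 CPM, as did keratin KRT7 (491, 47.3, 35.9 and 15.6 CPM), the chemokine CXCL8 (264, 2.28, 14.3 and 1.65 CPM) and E-cadherin CDH1 (191, 12.5, 8.3 and 3.82 CPM).

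The difference between donors 1 and 2 in untreated cells correlated between the disease groups with r = 0.369 across all tested genes and r = 0.502 across the 11565 genes with a mean of at least 5 CPM, and in treated cells with r = 0.283 across all tested genes. A batch by donor number, a shared mix of tubule segments or a bias shared with the diabetic TGFB1 replicate 1 library could each give this. The last was tested: with that library's difference taken out, the r over 11565 genes in untreated cells stayed at 0.502, so that bias does not account for it. The labels give no batch, so batch and segment mix were not told apart.

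Over 35 splits of the 8 libraries of a disease group into 4 and 4, fitted with a donor term, only the real one called as many genes. The real split called 8125 genes in non-diabetic and 7487 in diabetic cells, and the highest other 5988 and 1597. In both groups the highest other was that of donor 1 against donor 2, which cannot carry a donor term, so its count is not of the same form. With no donor term in any fit, the real split called 2986 genes in non-diabetic cells, fewer than the 5988 of donor against donor, so 2 of 35 splits called as many and chance is not excluded there by this count. In diabetic cells it called 4727 and the highest other 1597. That does not exclude chance, since these splits exchange libraries of 2 donors as if they were alike. In neither group can chance be excluded over donors, since each holds only 2 and their libraries may be technical repeats. Among the 18 splits that part each donor evenly and so keep the donor term, too few for a share under 0.05, the highest other called 4 genes in non-diabetic and 0 in diabetic cells (edgeR).

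Regions gained with TGFB1 lay beside raised genes more often than beside other genes, as in KANK4 and DHRS2. Longer peak lists after TGFB1 could give more gained regions beside every gene, and higher expression could go with open chromatin whatever the treatment. With lists of equal length the lower of the 2 odds ratios was 1.74, and within 10 classes of genes by mean expression the lower pooled odds ratio was 1.47 (95% interval 1.36 to 1.59), so neither accounts for the whole of it. The hypothesis that opening near genes goes with their induction is consistent with these tests, which do not show that a region acts on a gene.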
